A study of Mus musculus with 15 samples.

How the data were processed

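TCR alpha CDR3s were measured in 15 libraries of mouse CD8+ T cells: 5 Naive and 5 MP libraries from pooled spleen and lymph nodes, and 5 Tumour libraries from prostate tumours. Per the labels, cells were sorted as CD8b+ CD4neg CD44lo CD122neg (Naive), CD44hi CD122+ (MP) or CD8b+ CD4neg (Tumour), RNA was taken with Trizol, and iRepertoire made the libraries by arm-PCR, a multiplex RT-PCR. The labels quote the company on a Roche sequencing platform. The alignment, the calling of CDR3s and any error filter or molecular identifier are not given in the sources used here.

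The deposited values are counts of reads per CDR3 peptide, without normalization, as the authors deposited them, 1 list per library. The values were checked to be whole numbers, each peptide stood once in a library, the lowest listed count was 2 in every library, and no peptide held a stop or an unknown residue. A CDR3 that is not listed therefore had fewer than 2 reads, unless a filter that is not stated removed it. The sum of the counts was taken as the depth of a library. PCR reads without stated molecular identifiers are not independent molecules, so that floors and intervals cover counting error only. A fold against a group that does not list a CDR3 was computed against 3 reads per library. It is a lower bound where no such filter removed the CDR3.

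Calls per CDR3 were made with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1: a quasi-likelihood test with robust dispersions, the total reads as library size without TMM, CDR3s with at least 10 reads in at least 3 libraries, and a Benjamini-Hochberg adjusted p under 0.05. Each pair of groups was fitted alone. The labels do not say whether Naive and MP libraries of the same number share mice, and the libraries were treated as unpaired. The alternatives were TMM, DESeq2 1.42.0 with size factors from positive counts, a filter of at least 50 reads, a filter of at least 1 read in at least 2 libraries (below called no filter), thinning to the smallest library, a fold of at least 2, the library number as a block, and each library left out in turn. For repertoire values, CDR3s of fewer than 10 reads were left out, other similarity indices were used, and features were weighted by distinct CDR3. Leaving out CDR3s of fewer than 2 reads removed none.

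Values per library were computed in python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9. They were compared by exact permutation tests over all 252 splits of 5 against 5 libraries. The two-sided p is 2 times the smaller tail, and the smallest that 5 against 5 libraries allow is 0.00794. The expected number of distinct CDR3s was computed without random draws at 547665 reads for MP and Naive and at 574484 reads for Tumour and MP. Tests of features, regions and TRAJ segments were adjusted by Benjamini-Hochberg within each comparison, over 4 features, 3 regions and 39 segments.

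A CDR3 was given the TRAJ segment whose end it matched over its longest unique suffix of at least 4 residues, or at least 6 in an alternative. The segment ends were written from general knowledge and were not checked against a reference sequence. Of 43 ends listed, 39 were seen whole in reads and were used, 93.9 to 99.7% of the reads of each library were assigned, and TRAJ4, TRAJ7, TRAJ44 and TRAJ47 were not analysed here. The RefSeq gene table of GRCm38.p6 was used only for the names and order of the segments. Net charge counts K and R against D and E, and hydrophobic residues were F, I, L, M, V, W and Y at both middle positions of the loop.

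The groups, comparisons, tests, main alternatives and naming rule were fixed before the data were examined. By that rule, CDR3s stand in the place of genes. For MP against Naive, the 10 called CDR3s with the highest mean share in each subset and the 5 largest folds each way among called CDR3s were named. For tumours, the 10 CDR3s with the highest mean share among those with at least 10 reads in at least 3 tumours were named. Every TRAJ segment past the threshold was named, or the 5 with the largest differences if more than 10 passed. The iNKT and MAIT invariant CDR3s were always named, as CDR3s of other cells that the sort could hold.

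Other choices were made after values were seen. These were the set of hydrophobic residues, the middle positions, the TRAJ segments not analysed and the folding of possible reading errors. The counts of recurrent tumour CDR3s with their Fisher's exact test and the fits without MP 1 and MP 5 were among them. The use of calls without 1 Naive or MP library for the tumour reads, the leaving out of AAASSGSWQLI, the most abundant CDR3 of each library named outside the rule, the sequence families, the number of CDR3s shared with a tumour, and the doubled smaller tail as the two-sided p were also chosen then. The last replaced a count of differences at least as large in size. It changed no p-value of the 5 against 5 tests, but with 1 library left out it moved calls in both directions, as given with the alternatives.

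The calling was tested on simulated data with 200 changed CDR3s, of which 50 changed by 4-fold, 50 by 16-fold and 100 by a log2 fold of 8. In this order it recovered 28%, 46% and 66% for MP against Naive, 10%, 58% and 78% for Tumour against MP, and 42%, 70% and 92% for Tumour against Naive, with the right sign in 100%. Over the calls of all sizes, 4 beside 103 true ones, 8 beside 112 and 3 beside 148 were false, which is 3.74%, 6.67% and 1.99%. These shares depend on the mix of sizes and would be higher among small changes alone. They and the recovery also depend on the number of changed CDR3s, and the real fits called more than 200 in each comparison. Counts were drawn with the mean and the spread between libraries of the group in which a CDR3 was more abundant. This design was chosen after a first one, which held no change by a log2 fold of 8 and used the mean over both groups and the dispersions fitted by edgeR, had recovered 0% of 4-fold and 0% of 16-fold changes for MP against Naive and for Tumour against MP, and 7% and 52% for Tumour against Naive.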

Results

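The T cell receptor (TCR) alpha chains of CD8+ T cells were sequenced from male C57BL/6 mice that express a fixed transgenic TCR beta chain (TCRbtg), so that the receptors of different cells differ in the alpha chain. The values are read counts per CDR3 peptide, the hypervariable loop of the chain, which is written here without the conserved residues at its ends. Naive cells (CD44 low, CD122 negative) and memory-phenotype cells (MP; CD44 high, CD122 positive) were sorted from pooled spleen and lymph nodes of mice aged 9 weeks, with 5 libraries per subset. MP cells carry memory markers, and the series as titled concerns their self-specificity and their thymic precursors. Another 5 libraries came from CD8+ T cells of prostate tumours of TCRbtg males aged 27 weeks that carry the TRAMP transgene, a model of prostate cancer. The comparisons ask how the alpha chains of MP cells differ from those of Naive cells, and which of them are found in tumours.

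Naive libraries 1 to 5 held 702663, 547665, 574330, 552459 and 636322 reads. MP libraries 1 to 5 held 881988, 681565, 669453, 574484 and 684031 reads, and Tumour libraries 1 to 5 held 746511, 778694, 627205, 817759 and 943699 reads. In total 92219 distinct CDR3s were listed, each library listed a CDR3 from 2 reads upward, and 3 reads per library, used below as a floor, correspond to a mean share of 0.000498% in Naive, 0.000430% in MP and 0.000383% in Tumour libraries. No pair of libraries within a group was alike within counting noise.

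MP libraries held fewer distinct CDR3s on average and were less even than Naive libraries. Tumour libraries held the fewest on average and were the least even. A common depth evens the reads but not the cells. The number of cells sorted is not in the labels, so the values describe libraries and not the size of the cell populations. At 547665 reads per library, Naive libraries held 24340.4 ± 5516 distinct CDR3s and MP libraries 6892 ± 5607 (SD, n = 5 each), a difference of -17448 (exact two-sided permutation test, p = 0.00794). The Shannon entropy of read shares was 11.28 ± 0.106 bits in Naive, 8.95 ± 0.506 bits in MP and 6.48 ± 0.622 bits in Tumour libraries, and each pair of groups differed with an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 libraries allow. The 10 most abundant CDR3s took 10.5 ± 0.273% of reads in Naive, 24.8 ± 2.25% in MP and 46.2 ± 11.2% in Tumour libraries. At 574484 reads, Tumour libraries held 1485 ± 689 distinct CDR3s against 6914 ± 5628 in MP (exact two-sided permutation p = 0.0159).

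Within MP, libraries 1 and 5 held 12117 and 13845 distinct CDR3s at 547665 reads, and libraries 2 to 4 held 3365, 2201 and 2933. Without CDR3s of fewer than 10 reads the entropy difference of MP from Naive was -1.55 bits, against -2.33 with all CDR3s, the MP difference in distinct CDR3s from Naive was -3045 (exact two-sided permutation p = 0.0397) and the Tumour difference from MP -2734 (exact permutation p = 0.0159). Folding each CDR3 that lay 1 substitution from a CDR3 at least 100 times as abundant in its library removed 28.8 to 69.0% of the distinct CDR3s of Tumour libraries, 7.51 to 30.6% in MP and 6.98 to 7.19% in Naive libraries. Such CDR3s may be reading errors, which was not tested.

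**Figure D1:**
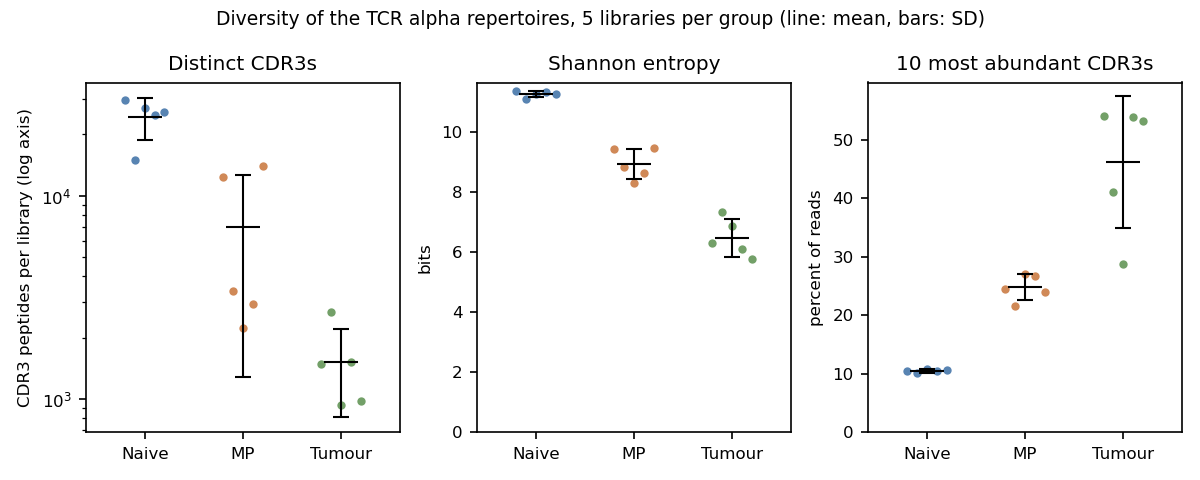
Distinct CDR3s per library from all reads (left, log axis), Shannon entropy in bits (middle) and percent of reads in the 10 most abundant CDR3s (right), with each library as a point, the mean as a line and the SD as bars. Naive libraries lie between 11.11 and 11.38 bits, MP libraries between 8.32 and 9.47 bits and Tumour libraries between 5.77 and 7.34 bits.

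The same abundant CDR3s recurred from library to library within each spleen and lymph node subset, and the subsets shared few of their reads. The Morisita-Horn index, which is 1 for identical and 0 for disjoint read shares, averaged 0.973 ± 0.0109 between Naive libraries and 0.916 ± 0.0267 between MP libraries, against 0.0578 ± 0.00843 between Naive and MP libraries. The mean within subsets exceeded that between subsets by 0.887 (exact one-sided permutation test, p = 0.00794). Of the 73948 CDR3s listed in Naive libraries, the 4440 listed in all 5 took 78.7 ± 0.548% of reads, and of the 25439 listed in MP libraries, the 483 listed in all 5 took 65.8 ± 1.39%. With the Jaccard index of CDR3 lists, which gives every CDR3 the same weight, the excess within subsets was 0.110 (exact one-sided permutation p = 0.00794).

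By read shares, tumours were far less alike than the libraries of either sorted subset. Pairs of tumours had a mean Morisita-Horn index of 0.220 ± 0.166, from 0.0484 for tumours 4 and 5 to 0.497 for tumours 2 and 4. By the Jaccard index of thinned lists the gap from MP was smaller. It was 0.0804 ± 0.0129 for pairs of tumours, 0.126 ± 0.0411 for MP and 0.224 ± 0.0191 for Naive pairs. Tumour pairs reached 0.0988 and MP pairs went down to 0.0744. Of the 6146 CDR3s listed in tumours, 70 were listed in all 5 and took 35.3 ± 9.24% of tumour reads, and 5280 were listed in 1 tumour only and took 35.3 ± 8.18%. The most abundant CDR3 differed in each tumour: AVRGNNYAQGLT took 14.7% of reads in Tumour 1, AARPPRYGNEKIT 14.5% in Tumour 2, AGRPPRYGNEKIT 4.19% in Tumour 3, ATASSNMGYKLT 20.8% in Tumour 4 and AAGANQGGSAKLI 22.6% in Tumour 5. In contrast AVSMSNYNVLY was the most abundant CDR3 in all 5 Naive libraries.

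**Figure D2:**
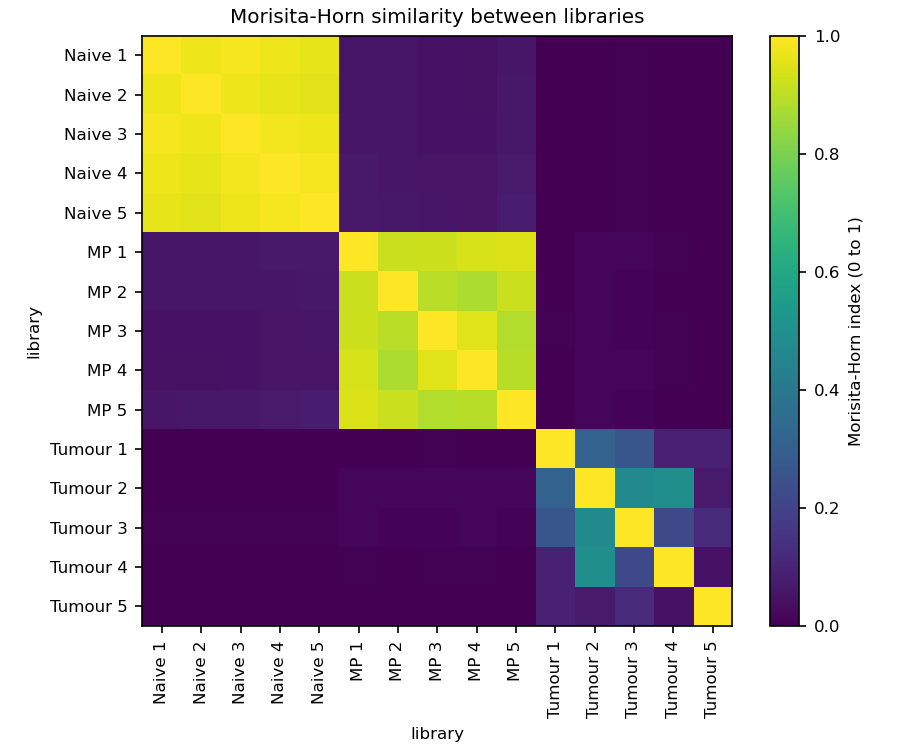
Morisita-Horn index (colour, 0 to 1) between each pair of the 15 libraries. Pairs within Naive lie between 0.954 and 0.988, pairs within MP between 0.876 and 0.952, pairs of tumours between 0.0484 and 0.497, and pairs from different groups at or below 0.0764.

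By reads, MP and Naive cells used largely different alpha chains. Of the distinct CDR3s of each MP library, 48.0 to 54.8% were also listed in Naive libraries. Of 5954 CDR3s tested with edgeR, 753 were higher and 2863 lower in MP at an adjusted p under 0.05. The 753 took 68.5 ± 1.48% of MP reads and 2.24 ± 0.151% of Naive reads, and the 2863 took 59.7 ± 0.571% of Naive reads and 0.944 ± 0.237% of MP reads (SD, n = 5). The calls came from these same libraries, so the direction of these shares follows from the choice of CDR3s. Of the 753, 340 were listed in all 5 MP libraries and 353 in no Naive library, and of the 2863, 2138 were in no MP library.

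The most abundant CDR3 of the MP subset was ALGSSNTNKVV, with a TRAJ34 end, at 5.31 ± 0.964% of MP reads and 0.0980 ± 0.0120% of Naive reads, a log2 fold change of 5.76 ± 0.37 (SE; edgeR adjusted p = 5.59e-05). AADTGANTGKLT, with a TRAJ52 end, took 4.55 ± 1.26% of MP and 0.0238 ± 0.00860% of Naive reads, a ratio of 191. ALASSNTNKVV and AMASSNTNKVV, which share the TRAJ34 end SSNTNKVV with ALGSSNTNKVV, took 2.99 ± 0.794% and 1.62 ± 0.353% of MP reads, with log2 fold changes of 8.56 and 6.48. 3 CDR3s with a TRAJ23 end were among the 10, namely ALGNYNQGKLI at 2.53 ± 0.280%, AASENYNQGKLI at 2.13 ± 0.525% and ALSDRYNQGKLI at 1.36 ± 0.206% of MP reads. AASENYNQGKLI was also common in Naive cells, at 0.469 ± 0.0892%, and had the smallest log2 fold change of the 10, 2.18 (edgeR adjusted p = 0.000811). Its call was lost without a count filter (edgeR adjusted p = 0.0559) and with the library number as a block (0.202). The others were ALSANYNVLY at 1.42 ± 0.387%, APSNSGTYQR at 1.32 ± 0.409% and AASNTGNYKYV at 1.16 ± 0.368% of MP reads, the last 2 with ratios to Naive of 963 and 1039.

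The CDR3s lower in MP were led by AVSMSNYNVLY, with a TRAJ21 end, at 2.07 ± 0.258% of Naive and 0.0111 ± 0.0118% of MP reads, a log2 fold change of -7.55 ± 1.39 (SE; edgeR adjusted p = 0.00125). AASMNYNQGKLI took 1.44 ± 0.236%, AVRDTNAYKVI 1.24 ± 0.0734% and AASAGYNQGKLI 0.922 ± 0.105% of Naive reads, with log2 fold changes of -5.67, -6.69 and -5.68. The fold of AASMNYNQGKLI rested on MP 3, at 0.138% of reads against at most 0.000794% in the other MP libraries. It reached -11.2 with 1 library left out. AALNNNNAPR, with a TRAJ43 end, took 0.904 ± 0.0921% of Naive reads and was listed in 1 MP library, at a ratio of 835. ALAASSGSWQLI, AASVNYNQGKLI, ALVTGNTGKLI, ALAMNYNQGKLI and AVSSSNTNKVV took between 0.682 and 0.805% of Naive reads, with log2 fold changes from -8.84 to -4.86. That of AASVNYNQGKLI, -6.07, rested on MP 5, at 0.0585% of reads against at most 0.000907% in the other MP libraries. With 1 library left out it reached -11.6. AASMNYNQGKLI, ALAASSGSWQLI and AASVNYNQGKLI, at edgeR adjusted p of 0.0315, 0.0321 and 0.0348, lost the call when any 1 Naive library was left out, with edgeR adjusted p from 0.0509 to 0.0594. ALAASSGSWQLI also lost it without MP 5 (edgeR adjusted p = 0.0582), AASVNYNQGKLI without MP 1 (0.0583), and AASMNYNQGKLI without MP 1 and MP 5 together (0.0608).

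The 5 largest log2 fold changes each way in the edgeR fit belonged to CDR3s that 1 subset did not list. A fitted value against no reads is no measured fold, and the bounds below are not a ranking, since listed CDR3s such as AASNTGNYKYV, at a ratio of 1039, lie above most of them. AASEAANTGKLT at 0.282 ± 0.0769% and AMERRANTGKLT at 0.237 ± 0.0484% of MP reads, both with a TRAJ52 end, were at least 566-fold and 476-fold higher in MP, measured against the floor of 3 reads per Naive library. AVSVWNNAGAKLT and ALSGTYQR were at least 318-fold and 290-fold higher. AHQNYGSSGNKLI was at least 680-fold higher, but its mean of 0.339 ± 0.705% rested on MP 5, where it took 1.60% of reads against at most 0.0636% in the others, and DESeq2 gave it no p-value. In the other direction AIAPSSNTNKVV, at 0.510 ± 0.0555% of Naive reads, was at least 1188-fold lower in MP, and ALEHPGYQNFY, AIATGYQNFY, ALSDGSNNRIF and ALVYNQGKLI were at least 549-, 487-, 446- and 443-fold lower.

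A stricter or looser count filter moved the number of calls, and so did leaving out MP 1 and MP 5 together, an alternative chosen after their larger number of CDR3s was seen. Without these 2 libraries 4867 CDR3s were tested, and 356 were higher and 3436 lower in MP. On simulated counts with 200 changed CDR3s among 5954, edgeR recovered 28% of 50 4-fold changes, 46% of 50 16-fold changes and 66% of 100 changes by a log2 fold of 8, so CDR3s without a call are not shown to be alike. The real fit called far more CDR3s than 200, so these shares need not hold for it.

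**Figure D3:**
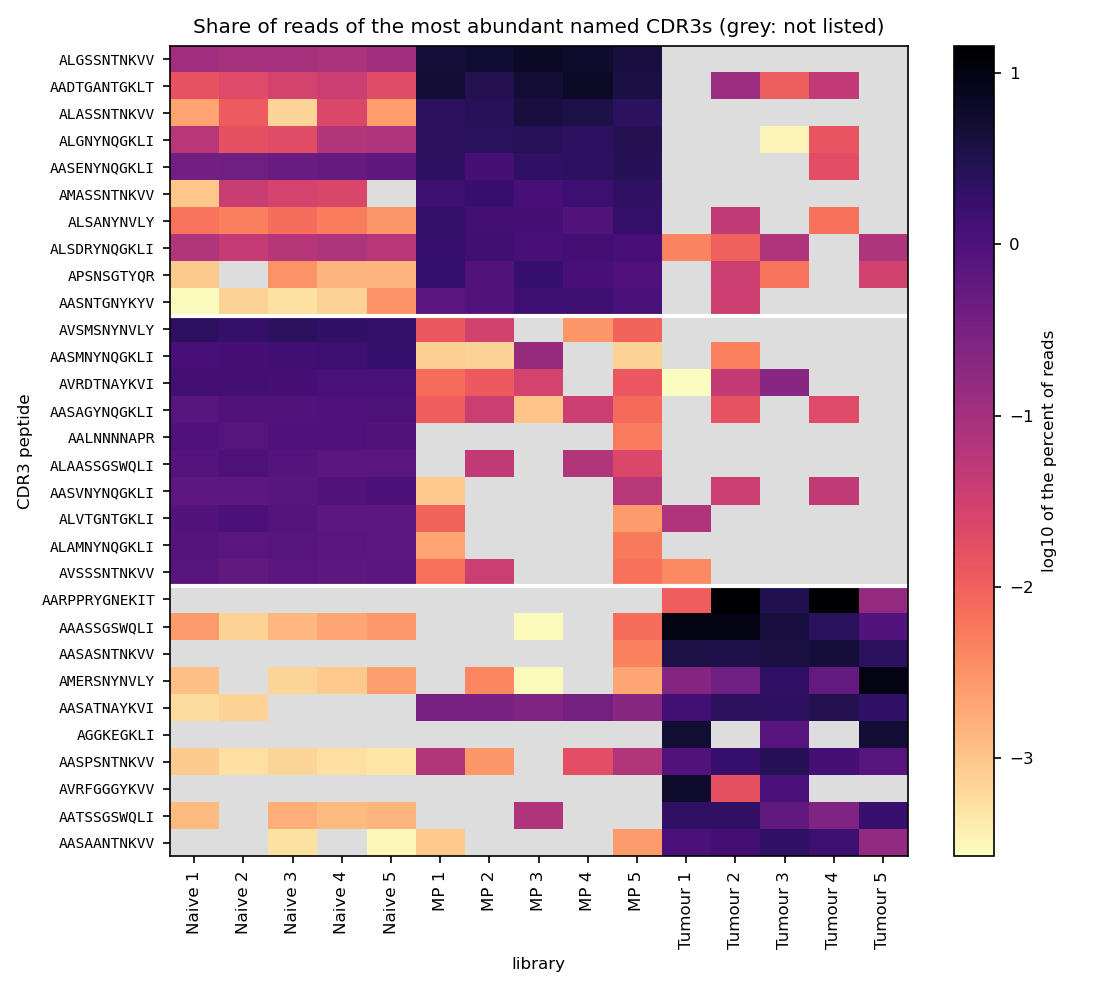
Percent of reads (colour, log10 scale, grey where a CDR3 is not listed) of the 10 most abundant CDR3s called higher in MP (top block), the 10 most abundant called lower in MP (middle block) and the 10 CDR3s with the highest mean share in tumours (bottom block) in each of the 15 libraries. ALGSSNTNKVV takes 4.08 to 6.59% of reads in every MP library and is not listed in any tumour.

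By reads, MP cells also differed from Naive cells in joining segment use, in part through abundant CDR3s named above. TRAJ34 took 19.7 ± 2.90% of MP reads against 10.4 ± 1.36% of Naive reads, TRAJ52 took 5.89 ± 1.48% against 1.57 ± 0.217%, and TRAJ26 took 6.69 ± 0.890% against 3.80 ± 0.206%. TRAJ43 went the other way, with 2.54 ± 0.250% in MP and 7.55 ± 0.375% in Naive, as did TRAJ30 with 3.75 ± 0.647% and 6.66 ± 0.447%. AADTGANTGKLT alone took 4.55% of MP reads, beside a TRAJ52 difference of 4.32 percentage points. ALGSSNTNKVV, ALASSNTNKVV and AMASSNTNKVV took 5.31%, 2.99% and 1.62% of MP reads, beside a TRAJ34 difference of 9.34 points. The TRAJ52 and TRAJ34 differences by read are therefore not separate from those of these CDR3s. In all, 9 of 39 segments were higher and 19 lower in MP, and the 5 named here had an adjusted exact two-sided permutation p of 0.0119. The 5' segments (TRAJ61 to TRAJ42), nearest the variable segments, took 18.1 ± 0.238% of MP and 25.7 ± 0.578% of Naive reads, and the middle segments (TRAJ41 to TRAJ22) took 66.1 ± 1.68% and 60.7 ± 0.808% (adjusted exact permutation p = 0.0119 each). The 3' segments (TRAJ21 to TRAJ1) took 13.9 ± 1.23% and 12.9 ± 0.648%, a difference that did not pass by reads with all libraries (adjusted exact permutation p = 0.143). The 3' difference passed without MP 4, at 1.53 percentage points (adjusted exact permutation p = 0.0317), and was -0.366 with at least 6 residues matched (0.579). Counted by distinct CDR3 instead of by read, the differences of TRAJ52 and TRAJ30 were -0.629 and 0.177 percentage points, opposite in sign to those by read, and 5 segments were higher and 12 lower. By that count the middle segments differed by 1.01 percentage points (adjusted exact permutation p = 0.389) and the 3' segments were 4.05 points higher in MP (0.0119).

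The MP loops were shorter and more positively charged. Read-weighted CDR3 length was 10.9 ± 0.0513 residues in MP and 11.2 ± 0.0359 in Naive, a difference of -0.343 (adjusted exact two-sided permutation p = 0.0106). Net charge was 0.615 ± 0.00785 in MP and 0.536 ± 0.0155 in Naive (adjusted exact permutation p = 0.0106). A cysteine inside the loop occurred in 0.274 ± 0.0449% of MP and 0.508 ± 0.0517% of Naive reads (adjusted exact permutation p = 0.0106), and a hydrophobic residue at both middle positions in 0.0973 ± 0.0510% and 0.0872 ± 0.0109% (adjusted exact permutation p = 0.698). Weighted by distinct CDR3, the length difference was -0.665 (adjusted exact permutation p = 0.0159), the cysteine difference turned to 0.229 percentage points higher in MP (adjusted exact permutation p = 0.0159), and the charge difference was 0.0219 (adjusted exact permutation p = 0.0529). Possible reading errors were not folded for these values. Folding removed 7.51 to 30.6% of distinct CDR3s in MP and 6.98 to 7.19% in Naive libraries. Whether the CDR3s removed were errors was not tested.

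CDR3s of invariant T cells, which a CD8 sort could hold, were rare. They were matched by the CDR3 peptide alone, without the variable segment, so that other T cells could carry them. The invariant CDR3 of iNKT cells had 0 to 5 reads in any Naive or MP library and none in tumours. The MAIT cell motif took 0.0189 ± 0.00368% of Naive and 0.00334 ± 0.00288% of MP reads (exact two-sided permutation p = 0.00794), and among tumours it was listed only in Tumour 2, with 60 reads.

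Tumour CD8+ T cells carried CDR3s that were rare or not listed in spleen and lymph nodes. With edgeR, 128 of 1666 CDR3s tested were higher and 1100 lower in Tumour than in MP libraries, and 158 of 4671 were higher and 4051 lower in Tumour than in Naive libraries. The 128 took 44.3 ± 5.80% of tumour reads and 0.374 ± 0.0498% of MP reads, and 79 of them were not listed in MP. The 158 took 48.9 ± 6.83% of tumour reads and 0.109 ± 0.00834% of Naive reads, and 70 of them were not listed in Naive. Both sets were called from these same libraries, so the direction of their shares follows from the choice. Tissue, age, genotype, library submission and the sort, which for Tumour had no CD44 or CD122 gate, all differ between Tumour and the other groups. They cannot be told apart. Without MP 1, 572 of 1048 CDR3s tested were lower in Tumour than in MP, and without MP 5, 587 of 1086. Without Tumour 2 or Tumour 4, 81 of 1533 and 84 of 1595 tested were higher. Without MP 1 and MP 5 together 642 were tested, of which 68 were higher and 225 lower in Tumour than in MP. Fewer CDR3s passed the count filter without these MP libraries. With the library number as a block 57 were higher and 265 lower, of 1666 tested. Tumour and MP libraries of the same number come from different mice, so that this block is arbitrary here.

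AARPPRYGNEKIT, with a TRAJ48 end, had the highest mean share in tumours, 6.38 ± 7.37%, from 0.0109 to 14.5%, and was at least 14849-fold higher than in MP, where it was not listed, as it was not in Naive. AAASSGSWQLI, with a TRAJ22 end, took 5.36 ± 4.12% of tumour reads, 0.00149 ± 0.00317% of MP and 0.00187 ± 0.000816% of Naive reads, a log2 fold change of 11.79 ± 2.76 over MP (SE; edgeR adjusted p = 0.0107) and of 11.47 ± 1.21 over Naive (edgeR adjusted p = 1.90e-05). Its MP share came mostly from MP 5, at 0.00716%. With 1 library left out, its log2 fold change over MP lay between 11.4 and 15.8. AASASNTNKVV took 2.35 to 4.50% of reads in each tumour, with a mean of 3.59 ± 0.798%, was listed in 1 MP library and no Naive library, and was at least 7221-fold higher than in Naive. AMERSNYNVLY took 2.54 ± 3.94%, of which most came from Tumour 5 with 9.47%. AGGKEGKLI at 2.13 ± 2.57% and AVRFGGGYKVV at 1.40 ± 2.55% were each listed in 3 tumours and in no Naive or MP library, and without MP 1 and MP 5 their calls over MP were lost (AGGKEGKLI edgeR adjusted p = 0.0704, AVRFGGGYKVV 0.0796). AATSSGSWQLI and AASAANTNKVV took 1.37 ± 0.890% and 1.21 ± 0.700% of tumour reads. The call of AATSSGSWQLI over MP (edgeR adjusted p = 0.0473) was lost when any 1 tumour, or any 1 MP library other than MP 3, was left out, with edgeR adjusted p from 0.0501 to 0.0875. It was also lost with TMM scaling (0.0820), with the stricter count filter (0.0567) and without MP 1 and MP 5 (0.130).

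AASATNAYKVI and AASPSNTNKVV were higher in MP than in Naive and higher again in tumours. AASATNAYKVI, with a TRAJ30 end, took 0.000260 ± 0.000360% of Naive, 0.289 ± 0.0524% of MP and 2.22 ± 0.574% of tumour reads. Its log2 fold change was 10.01 ± 1.41 for MP over Naive (edgeR adjusted p = 0.000662) and 2.94 ± 1.13 for Tumour over MP (edgeR adjusted p = 0.0304). AASPSNTNKVV took 0.000623 ± 0.000153%, 0.0320 ± 0.0355% and 1.48 ± 0.808%, with log2 fold changes of 5.64 ± 1.58 and 5.53 ± 1.86 (edgeR adjusted p = 0.0117 and 0.0183). With TMM scaling the Tumour over MP calls of both were lost (AASATNAYKVI edgeR adjusted p = 0.201, AASPSNTNKVV 0.0631), and without a count filter that of AASATNAYKVI was also lost (edgeR adjusted p = 0.163). With the library number as a block both lost the Tumour over MP call (AASATNAYKVI edgeR adjusted p = 0.243, AASPSNTNKVV 0.0724). That block is arbitrary for Tumour and MP libraries, which come from different mice. With the block AASPSNTNKVV also lost the call for MP over Naive (log2 fold change 4.26, edgeR adjusted p = 0.151). In contrast ALGSSNTNKVV, ALASSNTNKVV and AMASSNTNKVV were not listed in any tumour, which puts them at least 13860-, 7792- and 4221-fold lower there than in MP.

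By read shares, tumour libraries resembled MP libraries slightly more than Naive libraries, with low similarity to both. The mean Morisita-Horn index with the 5 tumours was 0.00713 ± 0.000491 over MP libraries and 0.00236 ± 0.000108 over Naive libraries, a difference of 0.00477 (exact two-sided permutation test over the 10 Naive and MP libraries, p = 0.00794). These SDs and this test take the tumours as fixed and do not cover the spread between tumours. Over pairs of libraries the index was 0.00713 ± 0.00466 for MP with Tumour, from 0.00229 to 0.0146. It was 0.00236 ± 0.00219 for Naive with Tumour, from 0.000663 to 0.00675, so the ranges overlapped. Within each tumour every MP library had a higher index than every Naive library. With libraries of any group left out in turn, the difference lay between 0.00329 and 0.00552. The difference was 0.00879 with the Bray-Curtis similarity and 0.0217 when the 10 most abundant CDR3s of each library were left out. By lists of CDR3s the direction depended on the measure. Thinned Naive libraries shared 328 ± 39.6 CDR3s with a tumour and thinned MP libraries 192 ± 99.1, a difference of -136 (exact two-sided permutation p = 0.0317), from lists of 24349 and 6891 CDR3s on average. The Jaccard index of thinned libraries, whose upper limit is lower for the longer Naive lists, gave a difference of 0.0113 in favour of MP. The number shared was added after the data were examined.

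By calls, the direction depended on the MP libraries used. CDR3s called higher in MP took 8.03 ± 3.02% of tumour reads and CDR3s called higher in Naive 2.66 ± 1.02%, a difference of 5.37 percentage points that was positive in 5 of 5 tumours (exact two-sided sign-flip permutation p = 0.063, the smallest that 5 tumours allow). With calls from the fit with the library number as a block the difference was 2.24 percentage points (exact sign-flip permutation p = 0.063). With calls made without MP 5 it was -2.14 percentage points (exact sign-flip permutation p = 0.3125), without MP 1 it was 3.42, and without MP 1 and MP 5 it was -6.52, from 4.60 ± 2.67% in MP calls and 11.1 ± 4.78% in Naive calls (exact sign-flip permutation p = 0.063). The CDR3 that moved most was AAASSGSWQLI, with 58 reads in 5 Naive libraries and 51 reads in 2 MP libraries, which had no call with all libraries and was called higher in Naive without MP 5 (edgeR adjusted p = 0.0101) and without MP 1 and MP 5 (0.0109). AASPSNTNKVV lost its MP call there. With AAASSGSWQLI left out, the difference without MP 1 and MP 5 was -1.18 percentage points (exact sign-flip permutation p = 0.6875). With calls from all libraries, counted by distinct CDR3 instead of by read, the difference was 0.109 percentage points (exact sign-flip permutation p = 0.875). CDR3s not listed in spleen and lymph nodes took 33.2 ± 11.8% of tumour reads, those listed there but too rare to test 35.6 ± 11.2%, and those tested without a call 20.5 ± 4.98%.

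**Figure D4:**
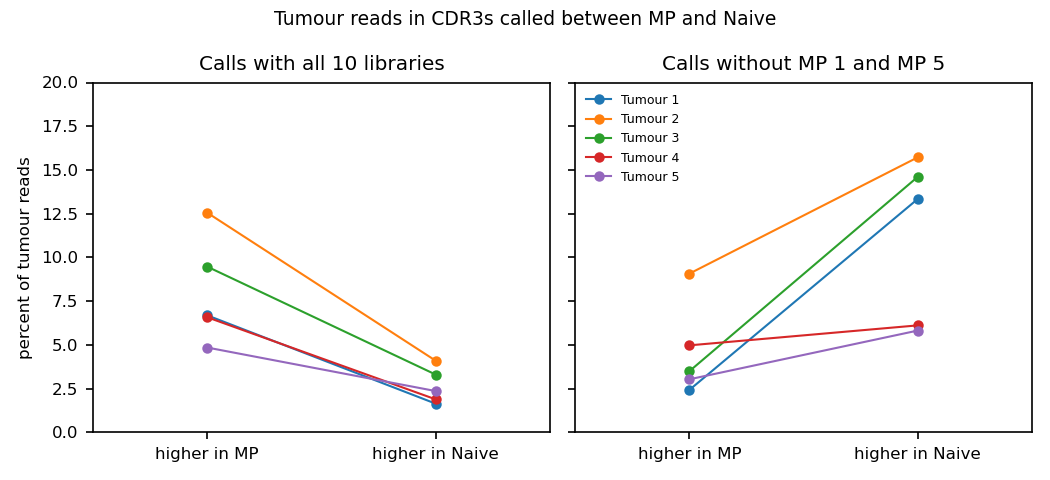
Percent of the reads of each tumour (lines) in CDR3s called higher in MP or higher in Naive, with calls from all 10 Naive and MP libraries (left) and without MP 1 and MP 5 (right). The difference is positive in 5 of 5 tumours on the left, with a mean of 5.37 percentage points, and has a mean of -6.52 on the right. Without the CDR3 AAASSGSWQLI, which is not drawn apart, the mean for the calls on the right is -1.18.

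CDR3s that recurred between tumours were a small set. At least 10 reads in at least 3 tumours were found for 182 CDR3s, which took 49.6 ± 6.56% of tumour reads, and 39 of them reached 10 reads in all 5 tumours. Of the 182, 84 were listed in both Naive and MP libraries, 28 only in Naive, 19 only in MP and 51 in neither. Of the 61 that could be tested between MP and Naive, 19 were called higher in MP and 7 higher in Naive, which is 2.52% of the 753 MP calls and 0.244% of the 2863 Naive calls (two-sided Fisher's exact test, odds ratio 10.6, p = 1.37e-08). With calls made without MP 1 and MP 5 they were 11 of 356 and 16 of 3436 (odds ratio 6.82, two-sided Fisher's exact p = 1.40e-05). With calls from all libraries the other 35 of the 61 had no call, with 5954 CDR3s tested in all. The odds ratios set MP calls against Naive calls only. A low share among Naive calls raises them as a high share among MP calls does. They do not show that MP calls hold more of these CDR3s than all CDR3s tested. CDR3s of the same libraries are not independent replicates.

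Joining segment use in tumours varied widely between animals. Against MP, TRAJ22 at 11.9 ± 8.64% and TRAJ30 at 9.94 ± 2.66% of tumour reads were 9.59 and 6.20 percentage points higher, and TRAJ33 at 0.970 ± 0.147% was 0.440 points higher. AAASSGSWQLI and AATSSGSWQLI, both with a TRAJ22 end, took 5.36% and 1.37% of tumour reads, so that much of the TRAJ22 difference lay in them. TRAJ23, TRAJ34 and TRAJ52 fell to 2.09%, 12.8 ± 3.21% and 0.711 ± 0.615% of reads, with differences of -12.1, -6.94 and -5.18 percentage points. TRAJ24, TRAJ13, TRAJ43 and TRAJ37 were also lower, with differences of -2.42, -2.34, -1.67 and -0.995 percentage points, and all 10 segments had an adjusted exact two-sided permutation p of 0.0310. Against Naive, 1 segment was higher and 14 lower, with TRAJ22 at 8.69, TRAJ23 at -13.9, TRAJ43 at -6.68, TRAJ31 at -2.85 and TRAJ37 at -2.71 percentage points (adjusted exact permutation p = 0.0281). The 3' segments took 23.0 ± 7.30% of tumour reads, 9.11 percentage points more than in MP and 10.2 more than in Naive (adjusted exact permutation p = 0.0238 each). The 5' and middle segments took 20.7 ± 10.6% and 53.7 ± 14.6%, and did not pass against MP (2.61 and -12.4 percentage points, adjusted exact permutation p = 0.563 and 0.131) or Naive (-4.98 and -6.99 points, 0.444 each). Without Tumour 1 both passed against MP, at 6.39 and -16.6 points (adjusted exact permutation p = 0.0159 each), and without Tumour 5 they were -1.13 and -7.27. Against Naive the 5' difference passed without Tumour 5, at -8.72 points (adjusted exact permutation p = 0.0238), and was -1.20 without Tumour 1, and the middle difference was -1.90 without Tumour 5 and -11.2 without Tumour 1. With any 1 MP library left out, or with Tumour 2, 4 or 5 left out, no segment passed against MP, where 4 against 5 libraries allow no exact permutation p below 0.0159, and none passed against Naive without Tumour 2 or without Naive 1, 3, 4 or 5. Counted by distinct CDR3, no segment passed against MP, TRAJ34 was 2.69 percentage points higher in Tumour than in MP (adjusted exact permutation p = 0.119), and the 3' difference was 1.74 from MP (adjusted exact permutation p = 0.619) and 5.78 from Naive (0.0119). By that count the 5' difference from Naive was -9.30 (adjusted exact permutation p = 0.0119).

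**Figure D5:**
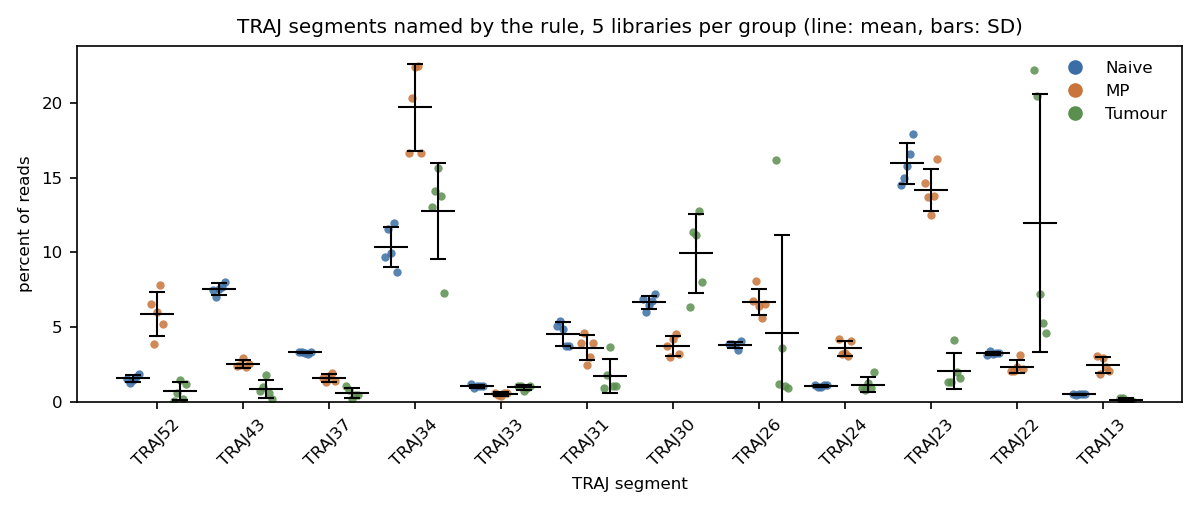
Percent of reads in each named TRAJ segment, from the 5' to the 3' end of the locus, with each library as a point, the mean as a line and the SD as bars, for Naive, MP and Tumour. TRAJ34 lies at 16.7 to 22.4% in MP libraries and 8.67 to 12.0% in Naive libraries, and TRAJ23 at 1.31 to 4.17% in tumours.

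Tumour loops were longer than MP loops, at 11.4 ± 0.113 residues by reads, a difference of 0.554 (adjusted exact two-sided permutation p = 0.0317). Against Naive the length difference was 0.211 and the charge difference 0.166 (adjusted exact permutation p = 0.0159 each), and weighted by distinct CDR3 the length difference was -0.214 (adjusted exact permutation p = 0.0106) and the charge difference 0.000945 (adjusted exact permutation p = 0.984). Loop cysteine, hydrophobic middle pairs and, against MP, net charge did not pass by reads, with adjusted exact permutation p from 0.0952 to 0.317. Weighted by distinct CDR3, cysteine was 1.60 percentage points higher than in MP and 1.83 higher than in Naive, and the hydrophobic pair 0.753 and 0.750 higher (adjusted exact permutation p = 0.0106 each). Folding removed 28.8 to 69.0% of the distinct CDR3s of Tumour libraries, against 6.98 to 7.19% in Naive libraries. Whether the CDR3s removed were reading errors was not tested. Features were not computed after folding, so these differences by distinct CDR3 cannot be told apart from reading errors. By reads without Tumour 4, cysteine passed at 0.512 points over MP (adjusted exact permutation p = 0.0317) and 0.278 over Naive (0.0423). Without Tumour 5, the hydrophobic pair passed at 1.27 and 1.28 points, and charge passed at 0.123 over MP (adjusted exact permutation p = 0.0212 each). Other libraries moved these differences the other way: the hydrophobic pair, at 3.99% in Tumour 1 against a mean of 1.10%, fell to 0.277 and 0.287 points without Tumour 1. Charge over MP fell to 0.0371 without Tumour 4, and cysteine over Naive to 0.0401 without Tumour 5. When 1 library was left out, the length difference from MP lay between 0.513 and 0.582 and its adjusted exact permutation p reached 0.0635.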

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

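The tests of read depth, of reading errors, of Naive cells in the MP sort and of carryover between tumour libraries were chosen after the results were seen, and that of other splits of the libraries before. What reading errors would show was written before that test was run.

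A value of 1 library lay far from the 4 others of its group, by Dixon's test with a critical value of 0.710 for 5 libraries, in 8 of 114 groups tested, and chance alone gives about 1 in 20. AHQNYGSSGNKLI took 1.60% of reads in MP 5 and between 0 and 0.0636% in the other MP libraries. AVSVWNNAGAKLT took 0.0235% in MP 2 and 0.170 to 0.210% in the others. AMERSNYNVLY took 9.47% of reads in Tumour 5 and 0.225 to 2.04% in the other tumours. AVRFGGGYKVV took 5.88% in Tumour 1 and between 0 and 1.13% in the others. TRAJ26 took 16.2% of reads in Tumour 1 against 0.954 to 3.62%, and TRAJ23 took 4.17% in Tumour 3 against 1.31 to 2.02%. The 5' TRAJ segments took 24.7% of reads in Naive 2 against 25.7 to 26.1%, and 18.5% in MP 1 against 17.9 to 18.0%.

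MP 1 and MP 5 listed more distinct CDR3s than MP 2 to 4, by a ratio of means of 4.63. Depth and reading errors are argued against, since the ratio was 4.58 at a common depth and 5.73 after folding each CDR3 that lay 1 substitution from a CDR3 at least 100 times as abundant. CDR3s that MP 2 to 4 did not list took 19.4% of reads in MP 1 and 19.6% in MP 5, while the 50 most abundant CDR3s called higher in Naive without MP 1 and MP 5 reached 6.03% of their Naive level in MP 1 and 1.91% in MP 5, against 1.65 to 2.65% in MP 2 to 4, which argues against Naive cells as the source of all the extra CDR3s. With the calls from all libraries the 50 most abundant had a ratio of 0.933 between MP 1 and 5 and MP 2 to 4, but those calls select CDR3s that are rare in every MP library, so that a small share of Naive cells in MP 1 and a difference within MP cells cannot be told apart. The number of cells sorted is not in the labels, and no biological explanation was tested.

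The same CDR3s recurred at over 1% of reads in at least 3 tumours, namely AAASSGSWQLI, AARPPRYGNEKIT, AASAANTNKVV, AASASNTNKVV, AASATNAYKVI, AASPSNTNKVV and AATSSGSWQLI, with a median share of 2.13%. Carryover of reads between tumour libraries is argued against as their source, since it would bring the abundant CDR3s of the donor library in proportion. In each of the 20 pairs of a donor and a receiving tumour, 3 to 16 of the CDR3s over 1% in the donor were not listed in the receiver. With 3 reads as the floor and the third lowest ratio of receiver to donor as the bound, carryover from the other 4 tumours gives at most 0.344% of any of the 27 shares over 1% of these CDR3s. Carryover of single CDR3s, or from libraries not used here, was not tested. Tissue, age, genotype, library submission and the sort without a CD44 or CD122 gate stay open as untested differences from the Naive and MP subsets.

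The number of calls in each comparison was set against that of other splits of its 10 libraries, with 100 splits in all. The other splits mix libraries of both groups, which raises the spread within each side. Low counts there therefore do not exclude chance, and 1 in 100 is the lowest share that the test allows. In MP against Naive the real split called 3616 CDR3s and the highest other split 0, in Tumour against MP 1228 and 541, and in Tumour against Naive 4209 and 612, and 1 split of each 100, the real one, reached the real count.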

How the results depend on the processing

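The fits without MP 1 and MP 5, the use of calls without 1 Naive or MP library for the tumour reads, the leaving out of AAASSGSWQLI and the number of CDR3s shared with a tumour were chosen after the results were seen. Of the alternative values for the main results, 514 kept direction and side of the threshold or, for counts, stayed within a fixed factor of the main count. A further 21 kept the direction but no longer passed, 15 came to pass, 57 counts moved beyond that factor and 15 values reversed. The 514 hold alternatives that could change nothing, such as the fold of at least 2 and leaving out CDR3s of fewer than 2 reads. Of the 30 named CDR3s of MP against Naive, 25 kept their call in every alternative. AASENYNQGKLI, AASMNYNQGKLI, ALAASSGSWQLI and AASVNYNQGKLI lost it in at least 1, and DESeq2 gave AHQNYGSSGNKLI no p-value. Where no reason is given below, the cause was not tested. A CDR3 with fewer than 2 reads is not listed, so depth limits which CDR3s are seen. Thinned to the smallest library, edgeR called 698 CDR3s higher and 2713 lower in MP against Naive, 121 and 1002 in Tumour against MP, and 154 and 3733 in Tumour against Naive. Depth was not varied in the simulated data.

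The labels do not say whether Naive and MP libraries of the same number come from the same mice. The residuals of same-numbered libraries correlated at 0.0107 to 0.0470, and 2 of 5 Naive libraries correlated best with the MP library of their own number, which neither shows nor excludes a pairing. With the number as a block the exact sign-flip permutation test over 5 pairs cannot go below p = 0.063, so losses in that test come from the design. At that bound stood richness MP minus Naive -17448, Shannon entropy -2.33, top 10 share 14.3 and tumour similarity 0.00477, and after adjustment length -0.343, loop cysteine -0.234 and charge 0.0791 (adjusted exact p = 0.0833) and the 5' segments -7.59 and middle segments 5.37 (adjusted exact p = 0.0938), with 0 TRAJ segments higher and 0 lower. With the block, edgeR called 57 CDR3s higher and 265 lower in Tumour against MP, whose same-numbered libraries come from different mice. The log2 fold change of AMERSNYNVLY for MP over Naive, without a call, turned to -1.47 with the block. The tumour reads in MP calls minus Naive calls were 2.24 percentage points with calls from that fit.

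Weighted by distinct CDR3, MP minus Naive was 0.229 for loop cysteine, -0.00299 for the hydrophobic pair, 0.0219 for charge, 4.05 for the 3' (passing, adjusted exact p = 0.0119) and 1.01 for the middle segments, 0.177 for TRAJ30 and -0.629 for TRAJ52, with 5 segments higher and 12 lower. Tumour minus MP was 1.60 for cysteine and 0.753 for the hydrophobic pair (both passing, adjusted exact p = 0.0106), -0.0209 for charge, 1.74 for the 3', -0.701 for the 5' and 1.41 for the middle segments and 2.69 for TRAJ34, with 0 segments higher and 0 lower. Tumour minus Naive was -0.214 for length, 1.83 for cysteine and 0.750 for the hydrophobic pair (both passing, 0.0106), 0.000945 for charge, -9.30 for the 5' (passing, 0.0119) and 2.42 for the middle segments, with 7 segments higher. Possible reading errors were not folded for these values by distinct CDR3. With at least 6 residues matched, the 3' difference of MP from Naive was -0.366.

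Without a count filter edgeR called 2289 higher and 14848 lower in MP against Naive, 521 and 4670 in Tumour against MP, and 391 and 21912 in Tumour against Naive. The stricter filter, which tests fewer CDR3s, called 438 and 846 in MP against Naive, 494 lower in Tumour against MP and 1069 lower in Tumour against Naive. Without MP 1 and MP 5 there were 356 higher in MP against Naive, of 4867 tested. In Tumour against MP there were 68 and 225, of 642 tested. The tumour reads in MP calls minus Naive calls were -6.52 percentage points without MP 1 and MP 5. They were -1.18 with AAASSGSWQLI also left out (exact sign-flip permutation p = 0.6875). The MAIT difference of Tumour from MP was 0.00107 for the exact peptide, and the log2 fold change of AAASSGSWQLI for MP over Naive was 0.0320 after thinning, both without a call there and with all libraries. The number of CDR3s shared with a tumour after thinning, MP minus Naive, was -136 (exact p = 0.0317), opposite in sign to the similarity by read shares and to the Jaccard index. The number shared and the Jaccard index both depend on the length of the lists.

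With 1 library left out in turn, MP minus Naive lay between -0.00297 and 0.0271 for the hydrophobic pair and between 0.688 and 1.53 for the 3' segments. Tumour minus MP lay between 0.513 and 0.582 for length, where 4 against 5 libraries allow no lone feature an adjusted exact p below 0.0635, and between 0.274 and 0.512 for cysteine, 0.277 (without Tumour 1) and 1.27 (without Tumour 5) for the hydrophobic pair, and 0.0371 (without Tumour 4) and 0.123 (without Tumour 5) for charge. It lay between -1.13 (without Tumour 5) and 6.39 (without Tumour 1) for the 5' and between -16.6 (without Tumour 1) and -7.27 (without Tumour 5) for the middle segments, and both passed without Tumour 1 (adjusted exact p = 0.0159). Tumour minus Naive lay between 0.0401 (without Tumour 5) and 0.278 (without Tumour 4) for cysteine, and between 0.287 (without Tumour 1) and 1.28 (without Tumour 5) for the hydrophobic pair. For the 5' segments it lay between -8.72 (without Tumour 5, passing at 0.0238) and -1.20 (without Tumour 1). The tumour reads lay between -2.14, without MP 5, and 6.09. Segments higher in Tumour than in MP numbered 0 to 6 and lower 0 to 11, and against Naive 0 to 5 and 0 to 15. CDR3s higher in Tumour than in MP numbered 81, without Tumour 2, to 122. Those lower numbered 572 of 1048 tested, without MP 1, to 1210 of 1533 tested, without Tumour 2. The two-sided p as 2 times the smaller tail was chosen after these values were seen. With it, the Tumour differences from MP passed without 1 library in 10 of 10 cases for richness, 10 of 10 for the 3' segments and 2 of 10 for length, and with a count of differences at least as large in size in 5, 5 and 10 of 10, with exact p, adjusted for the segments and length, up to 0.119, 0.0714 and 0.0317. Leaving out CDR3s of fewer than 2 reads moved nothing, since the lowest listed count is 2.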

Other observations

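The sequence families below were chosen after their values were seen, and the test of neighbours was written before its result, after the families had been seen.

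Some CDR3s of the named lists share most of their sequence. The families below were built around CDR3s abundant in MP or in tumours, so that a high share in that group follows from the choice, and no difference between groups was tested for them. CDR3s ending in SSNTNKVV, as ALGSSNTNKVV, ALASSNTNKVV and AMASSNTNKVV do, took 14.7 ± 1.77% of MP reads, 5.18 ± 0.703% of Naive reads and 2.22 ± 0.910% of tumour reads (SD, n = 5 each). CDR3s made of AAS, any residue and SNTNKVV, such as AASASNTNKVV and AASPSNTNKVV, took 6.27 ± 1.60% of tumour reads, 0.0801 ± 0.0604% of MP reads and 0.0144 ± 0.00311% of Naive reads. CDR3s ending in RPPRYGNEKIT, such as AARPPRYGNEKIT and AGRPPRYGNEKIT, took 7.26 ± 7.18% of tumour reads, from 0.0109 to 14.6%, in 16 distinct CDR3s, and were not listed in Naive or MP libraries.

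A hypothesis from these families was that abundant CDR3s may be more alike in tumours than in MP. It was tested as the percent of the 100 most abundant CDR3s of a library with a 1-substitution neighbour among them. The mean was 47.2 ± 5.81% in tumours and 51.2 ± 4.82% in MP, a difference of -4 percentage points (adjusted exact two-sided permutation p = 0.440), so that the test neither bears out nor excludes it.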
